A study of Bubalus bubalis with 6 samples.

How the data were processed

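Polyadenylated RNA was sequenced from 6 libraries of water buffalo (Bubalus bubalis) intramuscular adipocytes, the fat-forming cells that lie between muscle fibres. Per the labels' protocols, cells at 80% confluence received an adenovirus, the medium was replaced after 3 hours, an inducing medium was added 48 hours after transduction, and cells were collected after another 48 hours. RNA was extracted with TRIzol, selected with oligo-dT beads, fragmented, copied with random primers and sequenced on a DNBSEQ instrument. The virus carried either EGFP, the green fluorescent protein used as the control, or circPPARG1, a circular RNA named after the gene PPARG. Oligo-dT selection removes most circular RNA, since a circle has no poly(A) tail, and no value of circPPARG1 itself is reported here.

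The groups were taken from the sample titles, which name the virus and a replicate number. The genotype labels matched the titles. The treatment labels named the EGFP virus for all 6 libraries, including the 3 whose titles name circPPARG1, and were not followed for the grouping. The labels describe plating in triplicate and do not say whether the 3 libraries of a group came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical. No pair of libraries had identical values.

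The authors deposited 1 table with 19635 rows and 1 value column per library. Its header does not name the unit. The values were treated as FPKM (fragments scaled to the length of the gene model and to the number of mapped fragments), because the submitters' processing notes list HISAT2 and StringTie, the values carry decimals, and the deposited columns sum to totals that differ between libraries, which TPM would not. Versions, settings, genome build and annotation are not given in the sources used here. Each row carries a gene model identifier numbered along a chromosome. A gene name stands beside 13801 of the rows and none beside the other 5834. The read depth of each library is unknown, so no interval or detection limit that needs counts was computed, and tests written for counts were not run.

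The values were found not to belong to the gene identifiers of their rows. Rows were grouped into blocks by identifier, a block holding identifiers that differ only in their last digit, and the SD of log2(FPKM + 0.1) was taken within each of 1097 blocks with at least 5 rows at a mean of 1 FPKM or more. The same SD was taken with shuffled identifiers. The pairing of identifiers with names was checked by asking how often the names of consecutive identifiers lie within 5 protein-coding genes of each other in the RefSeq annotation of assembly NDDB_SH_1, which was used only for gene names and gene order. The names of 12131 rows matched a protein-coding RefSeq symbol. Whether each row still holds 1 gene across libraries was checked by Spearman correlation between libraries after the block means were subtracted. The report gives the outcome of these checks. Because of it, rows are described by the rank of their fold change and not by gene name, and no gene or pathway is said to have changed. Where a gene name appears, it is the label a row carries, and says nothing about that gene.

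The comparison of the groups does not need the names, since it sets the 6 values of a row against each other. Rows with a mean of at least 1 FPKM over the 6 libraries were kept and transformed to log2(FPKM + 1). A linear model with the group as its only term was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend and robust estimation). P-values were two-sided and adjusted over all rows tested by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low rows. The design, the filter, 18 lists of gene names and the rule for the items to be named were fixed before the data were examined. That rule took the 12 rises and the 12 falls with the largest fold change among rows with an adjusted p under 0.05, a mean of at least 1 FPKM and no overlap between the groups. It also asked for a gene symbol, for PPARG, and for members of each list. The request for a symbol was dropped and the list members are not named, because the symbols are detached from the values. The lists were tested as labelled with limma's camera (preset correlation of 0.01, then an estimated correlation) and with fry. A list with fewer than 5 tested rows was not tested.

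On simulated data with the real row means and spread, 200 of 11090 rows were changed at a time. The fit recovered 60.5% of rows changed 1.25-fold, 99.5% of those changed 1.5-fold and 100% of those changed 2-fold, with 4, 10 and 8 false calls. The fit to the real data called 3068 rows, many more than were changed in the simulation, so these rates need not carry over to it. Alternatives were a block for the replicate number, leaving out each library, no filter and a stricter filter, a pseudocount of 0.1, quantile normalization, median-of-ratios rescaling, eBayes without robust estimation, and a minimum absolute log2 fold change of 1. The checks of the identifiers were made with Python 3.11.15, pandas 2.3.3 and SciPy 1.17.1. These checks, the summaries over 10 classes of tested rows ranked by mean log2(FPKM + 1), and 100 draws of random rows in place of the lists were chosen after seeing the data.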

Results

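The study asked how overexpression of circPPARG1 alters gene expression while buffalo intramuscular adipocytes differentiate. Transcriptomes were measured on day 4 in 3 libraries from cells transduced with the circPPARG1 adenovirus and in 3 libraries from cells transduced with the EGFP adenovirus. Read depth is unknown. The deposited FPKM values summed to 369592, 365693 and 365576 in circPPARG1 replicates 1 to 3 and to 353099, 340165 and 353465 in the EGFP replicates. Between 10907 and 11211 of the 19635 rows stood at 1 FPKM or more in a library. Rows listed at 0 numbered 2097 to 2150 in the circPPARG1 libraries and 2341 to 2644 in the EGFP libraries.

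The values in the table did not belong to the gene identifiers and names beside them. Rows with neighbouring identifiers mostly had nearly equal values, most closely in circPPARG1 replicate 1. There the median SD of log2(FPKM + 0.1) within a block of neighbours was 0.0018. The same median was 0.193 and 0.190 in circPPARG1 replicates 2 and 3, and 0.365, 0.342 and 0.347 in the EGFP replicates. With shuffled identifiers it lay between 1.74 and 1.82. The median SD of a tested row between the 3 circPPARG1 replicates was 0.077 on the log2(FPKM + 1) scale, which is larger than the spread between neighbours in circPPARG1 replicate 1. Names followed the order of the identifiers, though the check used could not detect a shift of all names by a constant number of rows. Of 7166 pairs of consecutive named identifiers, 6380 (89.0%) had names that lie within 5 genes of each other in the RefSeq annotation, against 1 of 7166 random pairs. Values of a row were also tied to each other across libraries. After block means were subtracted, which left too little spread in circPPARG1 replicate 1 for it to be used, the Spearman correlation across rows was 0.61 between circPPARG1 replicates 2 and 3, 0.71 to 0.82 between EGFP replicates, and 0.27 to 0.42 across the groups. Without that subtraction, circPPARG1 replicate 1 correlated with replicates 2 and 3 at 0.99 over the tested rows, as those did with each other (0.99). Pairs across the groups reached 0.97 to 0.98. The 0.99 does not test circPPARG1 replicate 1 within blocks, since most neighbours there are so alike that exchanging their values would hardly change it. These correlations are across rows, which are not independent replicates.

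**Figure D1:**
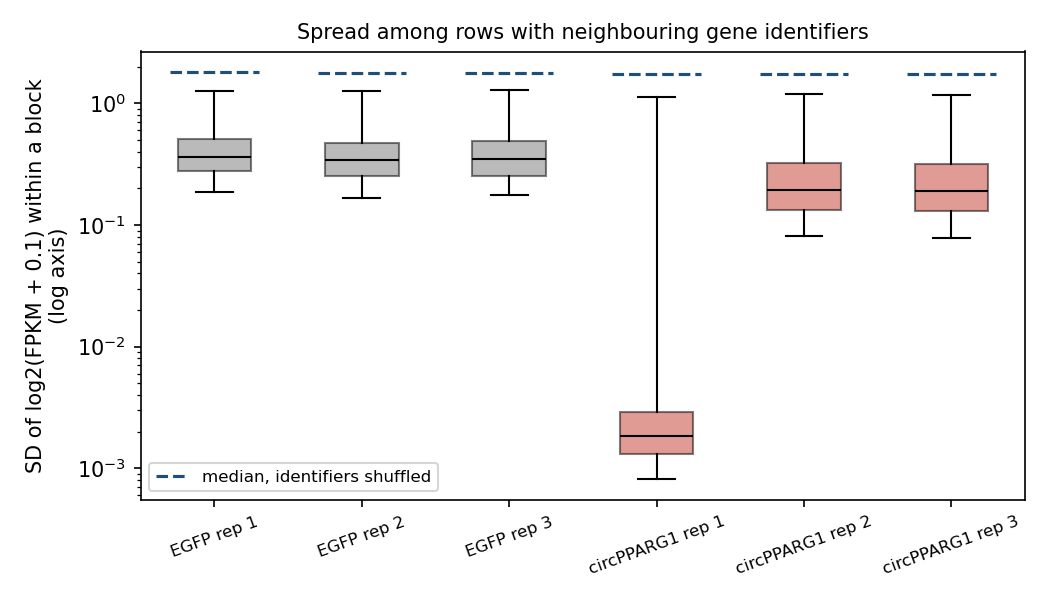
SD of log2(FPKM + 0.1) among rows with neighbouring gene identifiers, for 1097 blocks in each library (log axis); boxes span the quartiles, the line is the median, whiskers reach the 5th and 95th percentiles, and dashed lines give the median with shuffled identifiers. The median is 0.0018 in circPPARG1 replicate 1 and between 0.190 and 0.365 in the other 5 libraries.

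Levels under the names of well-known genes were mixed. These names, PPARG apart, were chosen after their values were seen. The row labelled ACTB, a cytoskeletal actin made in nearly every cell, had a mean of 2.74 FPKM over the 6 libraries. The row labelled RPLP0, a ribosomal protein, had a mean of 0.139 FPKM and the row labelled SPARC, a matrix protein of fibroblasts and adipocytes, 0.368 FPKM. The row labelled VIM, the intermediate filament of mesenchymal cells, read 0, 0.0072 and 0 FPKM in the EGFP replicates and 1.71, 1.28 and 1.31 FPKM in the circPPARG1 replicates. In contrast, the row labelled FTCD, a liver enzyme, had a mean of 122 FPKM and the row labelled ALB, serum albumin, 12.6 FPKM. The row labelled FABP4, an adipocyte fatty acid binding protein, had a mean of 24.2 FPKM. Rows labelled with adipocyte and lipid droplet markers had a median of 0.315 FPKM, at the 5.71th percentile of 10000 random lists of named rows of equal size. Rows labelled with macrophage and leukocyte markers had a median of 40.2 FPKM, at the 99.98th percentile. The other lists with a median in the top 10% of random lists were p53 targets and apoptosis (11.6 FPKM, 98.9th percentile), extracellular matrix (9.33 FPKM, 98.5th), smooth muscle and pericyte markers (8.80 FPKM, 95.6th), oxidative phosphorylation (6.73 FPKM, 94.98th) and fatty acid and triglyceride synthesis (6.25 FPKM, 93.0th), and so were 25 rows labelled with ribosomal proteins (6.99 FPKM, 95.9th). The remaining 11 of the 18 lists lay between the 9.42th and the 89.3th percentile. The random lists do not keep neighbouring identifiers together. Because of the match between values and identifier numbers, no level or change given here can be attached to a gene.

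The row labelled PPARG, the adipogenic nuclear receptor gene after which the circle is named, read 0.0459, 0.0269 and 0.0088 FPKM in circPPARG1 replicates 1 to 3 and 0.0686, 0.0282 and 0.0406 FPKM in the EGFP replicates. Its mean was 0.0272 ± 0.0185 FPKM (SD, n = 3) against 0.0458 ± 0.0207 FPKM (SD, n = 3), a log2 fold change of -0.03 that lies within the spread between replicates. It fell under the filter on low values, and without the filter limma gave an adjusted p of 0.57. Since labels and values were detached, this row does not measure PPARG.

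The comparison of circPPARG1 with EGFP was made on rows. One row dominated the circPPARG1 libraries, at 41851, 43670 and 44246 FPKM in replicates 1 to 3 against 12.8, 12.2 and 11.8 FPKM in the EGFP replicates. Its log2 fold change was 11.67 (SE 0.05, limma adjusted p = 1.23e-12), and it held 11.8% ± 0.411 (SD, n = 3) of the summed FPKM of the circPPARG1 libraries. A second row read 23.0 ± 0.279 FPKM with circPPARG1 and 0.313 ± 0.017 FPKM with EGFP (SD, n = 3 each), a log2 fold change of 4.19 (SE 0.07, limma adjusted p = 2.64e-08). Over the alternative fits the log2 fold change ranged from 10.07 to 11.78 for the dominant row and from 4.13 to 5.81 for the second. On the log2(FPKM + 1) scale no other row past the threshold rose 4-fold or more, and none fell that far. That scale compresses low rows. With a pseudocount of 0.1, 10 changed rows rose at least 4-fold, 4 of them at least 16-fold, and 1 fell at least 4-fold. The third rise read 1.46, 3.12 and 3.62 FPKM in the circPPARG1 replicates and was listed at 0, 0 and 0.171 FPKM in the EGFP replicates, and its log2 fold change was 1.77 with a pseudocount of 1 and 4.25 with 0.1. The fourth read 2.17, 3.08 and 2.29 FPKM against 0, 0.142 and 0 FPKM, with log2 fold changes of 1.74 and 4.27. The remaining 10 of the 12 leading rises had log2 fold changes from 1.77 down to 1.45, with limma adjusted p-values of at most 0.0018. The 12 leading falls ranged from -1.65 to -1.06, with limma adjusted p-values of at most 0.023. First among them was a row at 6.86 ± 0.774 FPKM with circPPARG1 and 23.6 ± 2.56 FPKM with EGFP (SD, n = 3 each, limma adjusted p = 0.00015). The most abundant of the 12 falls read 211 ± 7.85 FPKM with circPPARG1 and 529 ± 27.7 FPKM with EGFP (SD, n = 3 each), a log2 fold change of -1.32 (SE 0.06, limma adjusted p = 4.52e-05). The fall ranked second (log2 fold change -1.35, limma adjusted p = 0.023) did not pass without EGFP replicate 3 (0.068), circPPARG1 replicate 1 (0.056) or circPPARG1 replicate 2 (0.078).

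**Figure D2:**
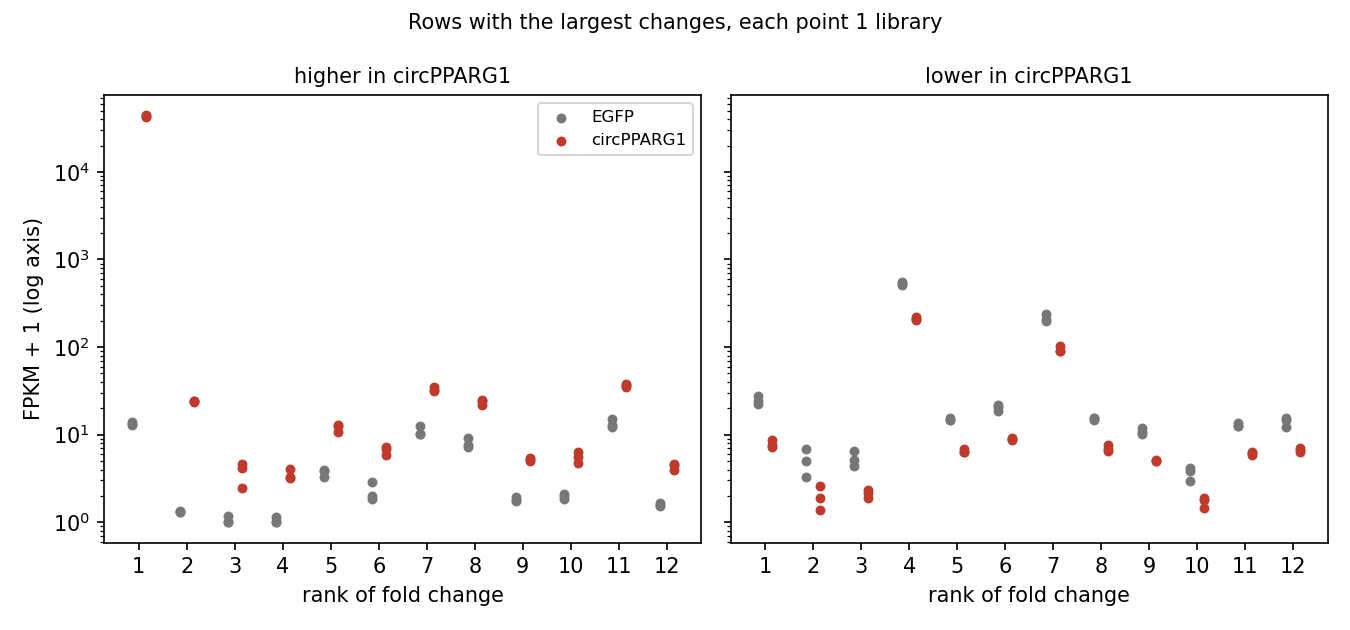
FPKM + 1 (log axis) of the 12 rows with the largest rise and the 12 with the largest fall, ranked by fold change on the horizontal axis; each point is 1 library, grey for EGFP and red for circPPARG1. The first rise stands at 41851 to 44246 FPKM in the circPPARG1 libraries and at 11.8 to 12.8 FPKM in the EGFP libraries.

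Of 11090 rows tested, 3068 (27.7%) differed between the groups at an adjusted p under 0.05 by limma, 2114 higher and 954 lower with circPPARG1. Changes were mostly small, with a median absolute log2 fold change of 0.38 among these rows. On the log2(FPKM + 1) scale 59 of them changed at least 2-fold, 42 higher and 17 lower. In the values as deposited, the groups did not overlap in 5114 rows (46.1%), where chance gives 10%. All circPPARG1 libraries were higher in 3513 of these rows and lower in 1601. The overlap was not recounted after rescaling, and a scaling difference between the groups could add to it. The first principal component held 57.9% of the variance and separated the groups. The direction depended on the scaling between libraries. Higher rows made up 68.9% of the changed rows as deposited, 45.2% after median-of-ratios rescaling (1210 higher, 1467 lower) and 50.3% after quantile normalization (1262 higher, 1249 lower). Under all 3 scalings, 1887 rows passed in the same direction, 1050 higher and 837 lower. Leaving out a library lowered the count by over 1.5 times for EGFP replicate 1 (1773 rows) and for circPPARG1 replicates 1 (1989 rows), 2 (1657 rows) and 3 (1565 rows).

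**Figure D3:**
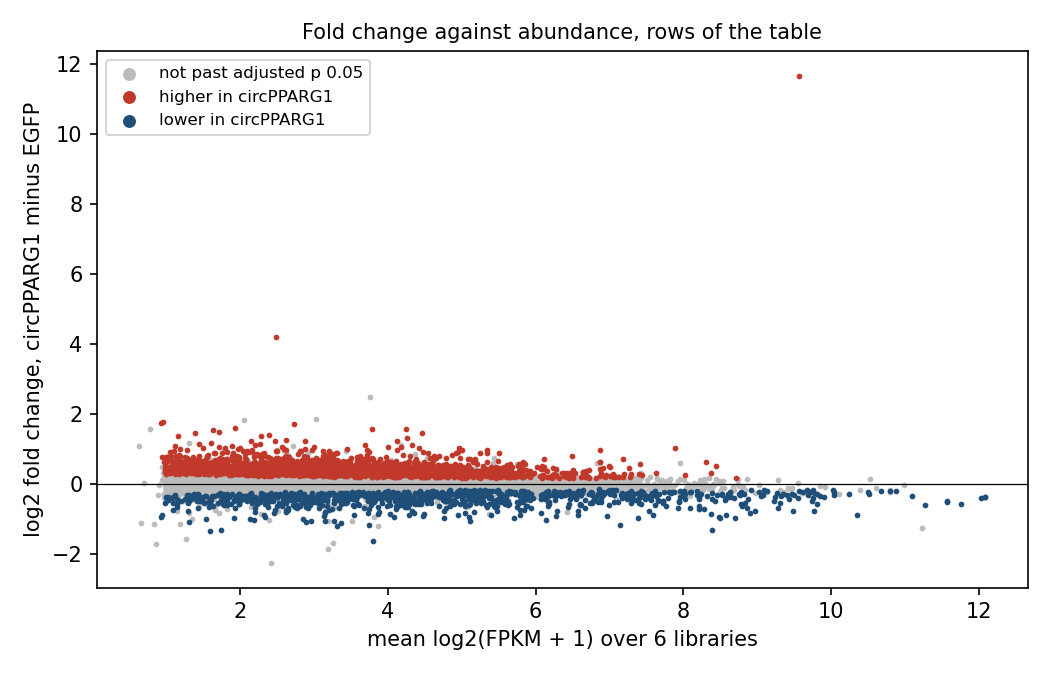
Log2 fold change on the log2(FPKM + 1) scale, circPPARG1 minus EGFP, against the mean log2(FPKM + 1) over 6 libraries for the 11090 rows tested; red rows were higher and blue rows lower with circPPARG1 at an adjusted p under 0.05 (limma), grey rows did not pass. The row at a log2 fold change of 11.67 and the row at 4.19 stand apart from the others past the threshold.

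The balance of rises and falls varied with abundance. Tested rows were ranked by abundance into 10 classes of 1109 rows. In the most abundant class, with a median of 91.8 FPKM, 290 rows fell and 123 rose, and the median log2 fold change was -0.06. In class 5, with a median of 8.04 FPKM, 62 fell and 248 rose, and the median was 0.11. After median-of-ratios rescaling the most abundant class held 423 falls and 51 rises. Each row was then centred on its own mean over the 6 libraries, and the median of that class was set against the median of all other rows. The difference, which a scaling factor common to a library moves little, was -0.08 ± 0.020 on the log2 scale in the circPPARG1 libraries. In the EGFP libraries it was 0.08 ± 0.037 (SD, n = 3 each). Because of the centring, the group means mirror each other, and only their distance carries information. The groups did not overlap (two-sided exact permutation p = 0.1, the smallest that 3 against 3 allows). With the dominant row set aside, the next 100 rows held 27.4% ± 0.546 of the remaining FPKM with circPPARG1 and 32.3% ± 0.853 with EGFP (SD, n = 3 each, two-sided exact permutation p = 0.1).

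**Figure D4:**
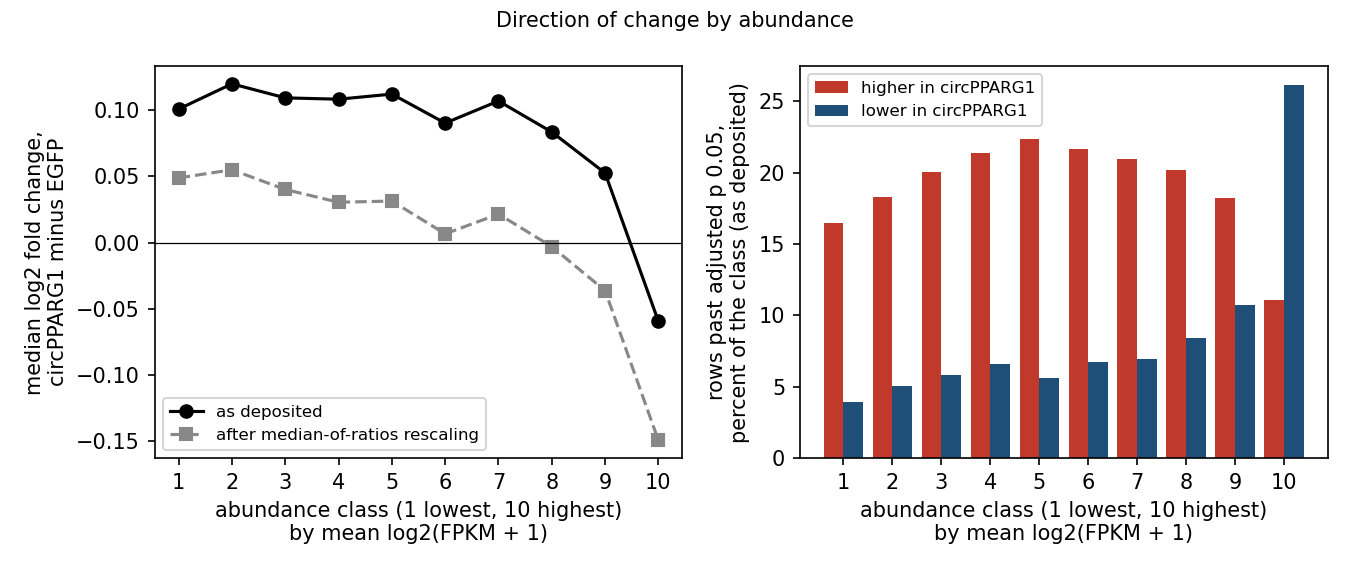
Left, median log2 fold change (circPPARG1 minus EGFP) in each of 10 abundance classes of the tested rows by mean log2(FPKM + 1), as deposited and after median-of-ratios rescaling; right, percent of each class that was higher (red) or lower (blue) with circPPARG1 at an adjusted p under 0.05 (limma), as deposited. In the most abundant class 26.1% of rows were lower and 11.1% higher.

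The fixed gene lists were tested under the deposited labels, and the outcome describes sets of mislabelled rows. Of 18 lists, 17 had at least 5 tested rows. None passed limma's camera at an adjusted p under 0.05 with the preset or the estimated correlation, 1 had an unadjusted p under 0.05, and the smallest adjusted p was 0.099. Fry, which does not compare a list with other rows, passed 8 of the 17. In 100 draws of random rows in lists of the same sizes, fry passed a median of 7 lists and camera a median of 0. Of 200 list entries, 66 passed limma over all rows and 73 passed when adjusted over the list alone.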

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

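All alternatives here were chosen before the data were examined. The 24 rows with the largest changes kept their direction in all 303 alternative fits and passed the threshold in 299. The other 4 fits concern the fall ranked second, which did not pass with the replicate block (adjusted p = 0.063) or without any 1 of 3 libraries. The 24 rows were chosen from these same data for large changes and groups that do not overlap. Leaving out a library or changing the pseudocount therefore could not reverse their direction. The block, the filters and eBayes without robust estimation left their fold changes as they were. Only quantile normalization and median-of-ratios rescaling could have reversed a direction. The count of 3068 changed rows stayed within 1.5 times of that under quantile normalization, median-of-ratios rescaling, both filters, a pseudocount of 0.1 and eBayes without robust estimation. Leaving out 1 library gave 1565 to 3894 changed rows, 1052 to 2651 higher and 513 to 1243 lower, with fewer samples in each such fit. Rows that rose numbered 1262 with quantile normalization and 1210 with median-of-ratios rescaling, against 2114 as deposited, and rows that fell numbered 1467 with the latter, since both methods centre the libraries on each other. A minimum absolute log2 fold change of 1 left 59 rows, 42 higher and 17 lower. Between 0 and 1 mislabelled lists passed camera when a library was left out (1 without EGFP replicate 1), and 8 passed fry. The row labelled PPARG moved from -0.03 to -0.20 on the log2 scale with a pseudocount of 0.1, which weighs values near 0 more.

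The replicate block gave 3066 changed rows, 2100 higher and 966 lower, and 0 lists. Libraries with the same number had deviations from the group means that correlated at 0.13, 0.16 and 0.06 across rows. Each of the 6 libraries correlated best with its own number, a weak hint from the data that the labels do not explain. These matches share the same correlations and are not independent. The margin was small for EGFP replicate 3, at 0.06 with circPPARG1 replicate 3 and 0.05 with circPPARG1 replicate 1. The count alternatives planned for a table of counts were not run, because the values are not counts. Read depth is unknown, so its limits could not be assessed.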

Other observations

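The tests in this part were chosen only after the results they concern were seen.

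Values that follow the numbering of the identifiers may come from a sort that moved the values and left the identifiers in place. Circumstances that produce this order can be simulated. The keys were not the identifiers as deposited. Their prefix evm.model was replaced by evm.TU and gaps in the numbering were filled, which gave 22960 assumed keys. Both choices are assumptions that affect the order. The keys were placed in a simulated Python 2 dictionary, which lists its keys by hash value, so that keys differing in their last digit come out close together. The Spearman correlation with that order across rows was 0.934 for circPPARG1 replicate 1 and 0.906 to 0.913 for the other 5 libraries, whose values follow those of replicate 1, and 0.006 to 0.008 with a shuffled order. This correlation hardly separates replicate 1 from the others, and it is the spread between neighbours that sets it apart. Other readings were argued against by the tables. Neighbouring genes that are expressed alike would be about as alike in each replicate. The spread between neighbours, however, was 105.9 times larger in circPPARG1 replicate 2 than in replicate 1. Gene names scattered over the identifiers would not leave 89.0% of consecutive names as neighbours in RefSeq. A shift of all names by a constant number of rows would leave them so, and this share cannot decide on it. How the table was made remains a hypothesis, and the sort does not allow the right identifier to be put back.

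The row at about 43256 FPKM in the circPPARG1 libraries is open to more than 1 reading. The 5 other rows that were at least 16-fold higher by mean FPKM + 0.1 held 0.011% of the summed FPKM, against 11.8% in this row. That argues against another cell type with many abundant transcripts of its own among these gene models. It cannot decide on RNA of another organism, since transcripts that match no gene model of the table would not be counted. Nor can it decide on a cell type whose abundant transcripts these cells also make, since those would not pass 16-fold. Reads of the transduced insert counted to its host gene is a candidate explanation that cannot be told apart from a response of the cells, because the gene of this row is not known. The row stood at 12.2 FPKM in the EGFP libraries, so these libraries also held reads for it. Whether those reads came from the control cells themselves was not tested. The level varied little between the circPPARG1 libraries, with a coefficient of variation of 2.89%.

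More rows rose than fell in the values as deposited, and the most abundant rows fell against the others. A scaling factor between the groups remains open for the excess of rises: after median-of-ratios rescaling 45.2% of changed rows rose, but that method centres the libraries on each other, so it cannot be told apart from a real excess. The fall of the abundant rows is another matter, since a single factor would move abundant and other rows alike, and the most abundant of 10 classes of rows moved against the others by -0.16 on the log2 scale. The dominant row, if it only took fragments from the others, would lower them, against the direction of the observed median of 0.08. Such an effect would run counter to the excess of rises. By the row's share of summed FPKM the shift would be -0.18. The row's share of fragments cannot be computed, because the length of its gene model is not known, so the size of that effect is open. Without this row the summed FPKM was lower with circPPARG1 (321330 to 327741) than with EGFP (340152 to 353454), although the median row rose. What stays open for the abundant rows is whether it is a response to circPPARG1 or a difference between the 2 sets of libraries that goes with the groups, and no biological explanation could be tested without gene names.

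Of the 10 splits of the 6 libraries into 3 and 3, only the real one (1 of 10) gave as many changed rows. The real split gave 3068 rows and the highest of the others 3. Every other split puts libraries of both viruses on each side, so the group difference adds to the spread and lowers the count. The 3 is therefore not a baseline of false calls. With 10 splits no share under 0.05 can be reached.

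Some rows were far off in a single library. In 8 rows 1 library stood at least 10-fold below each of the other 5, all of which were at 1 FPKM or more, and in 5 rows 1 library stood at least 10-fold above each of the others. These 13 rows were spread over all 6 libraries.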
